A study of Homo sapiens with 9 samples.

How the data were processed

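RNA was sequenced in 9 libraries of cells labelled H441, 3 per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with a NEBNext Ultra RNA kit. The submitters' processing notes list HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 without saying what each was used for. Per the file headers, the deposited table holds FPKM, fragments per kilobase of gene scaled to the size of each library, as computed by the authors, beside NCBI gene IDs, gene lengths and positions. The sequence accessions in the table are those of GRCh38. The strand setting used in counting is not given in the sources used here, so values of genes that overlap on opposite strands, and of near-identical copies of a gene, are uncertain.

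The table has 45754 genes, of which 20046 were typed as protein-coding and 14784 as lncRNA, and 339 were loci without a name. Another 28 names had been turned into dates and were restored from their gene IDs. The scale of the values was checked by multiplying FPKM by gene length. Within each library 100% of the values under 300 fragments came within 0.01 of a whole multiple of 1 step, so that fragments per gene could be recovered. The libraries held 16720414 to 18738947 recovered fragments, or 92.3 to 93.9% of the totals by which the values had been scaled. For a gene of 2 kb, 1 fragment was worth 0.0249 to 0.0280 FPKM. Intervals given here cover the spread between libraries and not differences between experiments.

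Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 12775. Values were analysed as log2(FPKM + 1), so that fold changes of genes with few fragments are understated. A change of 2-fold or more means here a difference of at least 1 on this scale. Some genes of low FPKM that changed by more in FPKM are therefore not counted. A linear model with 1 term per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with an intensity trend and robust empirical Bayes. Each compound was compared with control and the compounds with each other. P-values were adjusted over all tested genes by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Errors are standard errors of the model (SE) or standard deviations (SD), with n = 3 libraries per group, and intervals are 95% intervals. Labels do not state that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical in part.

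Gene lists for 46 pathways, responses and lineages, and 8 lists of cell type or cell line markers, were written from general knowledge. Their 999 entries were matched to the table by symbol, with older symbols where the table has them, and 0 stayed unmatched. Each of the 46 lists was tested against the other genes with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list, and fry, were run beside it. Calls within a list were also counted with p-values adjusted over the list alone, and where no such count is printed beside a list's count over all genes it was the same.

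Single genes were named by a rule. Per comparison it took protein-coding genes that were called, had a mean of at least 5 FPKM in the higher group and showed no overlap between the libraries of both groups. Of these it took the 6 largest rises and the 6 largest falls, then the 3 members with the largest change from each list holding at least 3 such genes, in order of the camera p, until about 30 genes were named. Other list members are named as examples of their list, chosen after their values were seen. The lists, this rule, the test, the comparisons and the other settings to be tried were fixed before the data were examined.

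The number of genes called for both compounds was set beside the number expected from the counts and beside 100 simulations of unchanged groups that shared the control libraries. The pipeline was tested on simulated data with known changes. In the simulation of the BSGL comparison 44% of changes of log2 0.25, 90% of 0.5, 98% of 1 and 100% of 2 were recovered, with 15 false among 180 calls. In that of the RSGL comparison the shares were 50%, 90%, 100% and 100%, with 8 false among 178 calls. Both simulations took 1 dispersion for all genes and left out genes with few fragments as changed genes. Their larger changes ease the adjusted threshold, so the share found among real BSGL changes may be lower. Of the simulated lists without a change, 0 of 230 were called by camera. The simulated genes were drawn independently of each other, so this could not show false calls that arise from correlation within a list.

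Other settings changed the pseudocount, the filter, the scaling between libraries, the model's options, the genes tested, the fold change required and the libraries included. Count models (edgeR and DESeq2) were also intended and were not run, because the table holds FPKM. After seeing the data, limma-voom on the recovered fragments, a restriction to genes on the primary chromosomes, and list tests without each library in turn were added. Prepared tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9. No library was left out.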

Results

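Gene expression was measured by RNA sequencing in 9 libraries of human cells labelled as H441, a lung adenocarcinoma line. The cells were exposed for 24 h to 10 µM of the compound BSGL, to 10 µM of the compound RSGL, or to 0.1% DMSO as the solvent control, with 3 libraries per group. The control libraries held 17749838, 18193216 and 17863877 fragments in genes, the BSGL libraries 18738947, 17490833 and 18065465, and the RSGL libraries 18513691, 16720414 and 16903016. Between 12213 and 12338 genes reached 1 FPKM per library. On a principal component analysis, the first component held 59.6% of the variance and set the RSGL libraries, at 30.3 to 31.2, apart from the other 6, at -16.5 to -14.2. The sample labels disagree on the cells. The cell line is given as H441 for every library, while a genotype tag names H460 for the control and BSGL libraries and A549 for the RSGL libraries.

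Genes that mark the lung lineage for which H441 is known were close to absent. Of 9 such genes, among them NKX2-1, the lineage transcription factor, and SFTPB, a surfactant protein, 0 reached 1 FPKM in at least 3 libraries. NKX2-1 was at 0.06 FPKM or lower in each library, SFTPB at 0.039 or lower, and the highest value, 1.00 FPKM, was that of NAPSA in 1 BSGL library. Of 12 genes known to be high in lines with mutant KEAP1, such as A549 and H460, 10 passed the filter, and the median over all 12 was 111 FPKM. AKR1B10, an aldo-keto reductase, averaged 373.5 FPKM in control, and the aldehyde dehydrogenase ALDH1A1 averaged 1961 FPKM. These levels bear on every comparison, since the identity of the cells stays in doubt. Among markers of other cell types, 3 of 9 fibroblast, 0 of 7 endothelial, 1 of 7 T cell, 2 of 8 macrophage, 2 of 8 neuroendocrine and 1 of 7 basal genes passed the filter. Under RSGL the macrophage marker CD68, a lysosomal protein also made by epithelial cells, rose from 40.2 to 118.8 FPKM, CD14 fell, and the basal marker SOX2 fell from 8.17 to 1.85 FPKM. The fibroblast markers COL1A1, from 2.22 to 0.668 FPKM, and THY1, from 3.44 to 2.84 FPKM, fell, and the neuroendocrine marker CHGB rose from 6.20 to 7.54 FPKM.

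**Figure D1:**
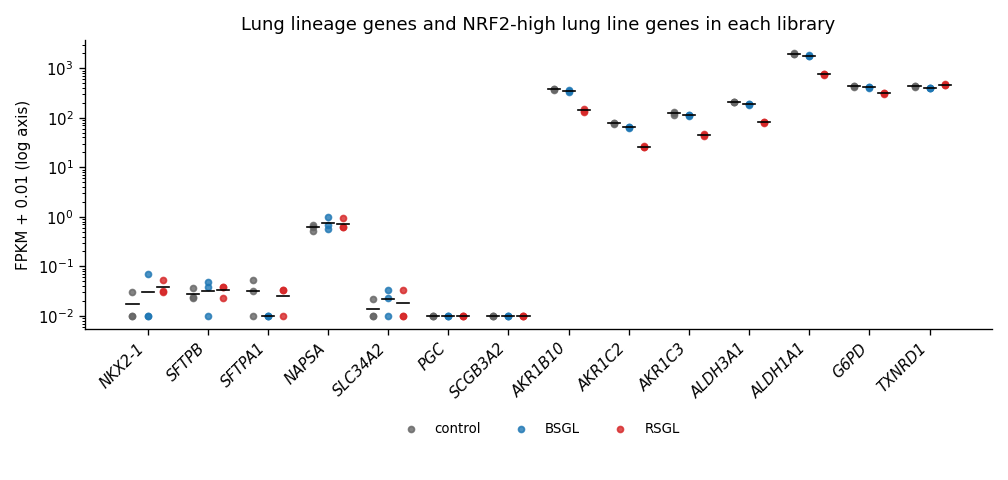
Expression of cell line marker genes in the control, BSGL and RSGL libraries, as FPKM + 0.01 on a log axis; each point is 1 library and each line a group mean (n = 3). NKX2-1 and SFTPB lie near the bottom of the scale in all 3 groups, while ALDH1A1 and AKR1B10 lie above 100 FPKM.

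The comparison of BSGL with control asks which genes the compound changed in these cells. Changes were few and small. ANGPTL4, a secreted inhibitor of lipoprotein lipase and a target of PPAR receptors, rose most, from 7.64 ± 0.42 to 12.3 ± 1.74 FPKM (SD, n = 3), a log2 change of 0.62 (95% interval 0.44 to 0.80). SCD, the desaturase that makes monounsaturated fatty acids, fell from 95.2 ± 2.07 to 73.8 ± 2.01 FPKM, and FADS2, a desaturase of polyunsaturated fatty acids, from 54.2 ± 1.6 to 42.0 ± 2.11 FPKM. INSIG1, which holds the sterol sensor complex in the endoplasmic reticulum, fell by 0.40 on the log2 scale (SE 0.0453). CPT1A, which admits fatty acids to mitochondria for oxidation, rose by 0.25 (SE 0.0339).

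In all, limma with Benjamini-Hochberg adjustment called 11 of 12775 genes, 6 higher and 5 lower. The adjusted p was 0.0343 for CPT1A and 0.0286 for each of the other 10. Beside ANGPTL4 and CPT1A, the genes that rose were CPA4, a carboxypeptidase (log2 0.37, SE 0.0448), G0S2, an inhibitor of triglyceride breakdown (0.36, SE 0.0474), SFRP1, a secreted Wnt antagonist (0.29, SE 0.0379), and the cytokine IL11 (0.28, SE 0.0358). Beside INSIG1, SCD (-0.36, SE 0.041) and FADS2 (-0.36, SE 0.0469), the genes that fell were CYP1B1, a monooxygenase induced by the aryl hydrocarbon receptor, at 106.7 and 86.4 FPKM (-0.30, SE 0.0362), and AKR1C2, an aldo-keto reductase (-0.26, SE 0.0323). The copies AKR1C1 to AKR1C3 are near-identical, so the level of AKR1C2 is uncertain. In each of the 11 genes the 3 BSGL libraries lay apart from the 3 control libraries, as did 12.8% of all genes where chance gives 10%. At an unadjusted p under 0.05 there were 857 genes, where 639 would be found by chance. Of the 11 genes, 0 changed by 2-fold or more, and limma-voom on recovered fragments, chosen after seeing the data, called 31 genes, 10 higher and 21 lower. Of the 11, G0S2 was lost with voom (adjusted p = 0.225) and the other 10 were kept.

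The positions of these genes are on GRCh38. ANGPTL4 (gene ID 51129) lies on chromosome 19 at 8364127 to 8374375, CPA4 (51200) on chromosome 7 at 130293134 to 130324180 and G0S2 (50486) on chromosome 1 at 209675325 to 209676390. SFRP1 (6422) lies on chromosome 8 at 41261957 to 41309471, IL11 (3589) on chromosome 19 at 55364382 to 55370463 and CPT1A (1374) on chromosome 11 at 68754620 to 68844410. INSIG1 (3638) lies on chromosome 7 at 155297776 to 155310235, SCD (6319) on chromosome 10 at 100347015 to 100364831 and FADS2 (9415) on chromosome 11 at 61816203 to 61867354. CYP1B1 (1545) lies on chromosome 2 at 38067603 to 38076181 and AKR1C2 (1646) on chromosome 10 at 4987775 to 5018033.

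**Figure D2:**
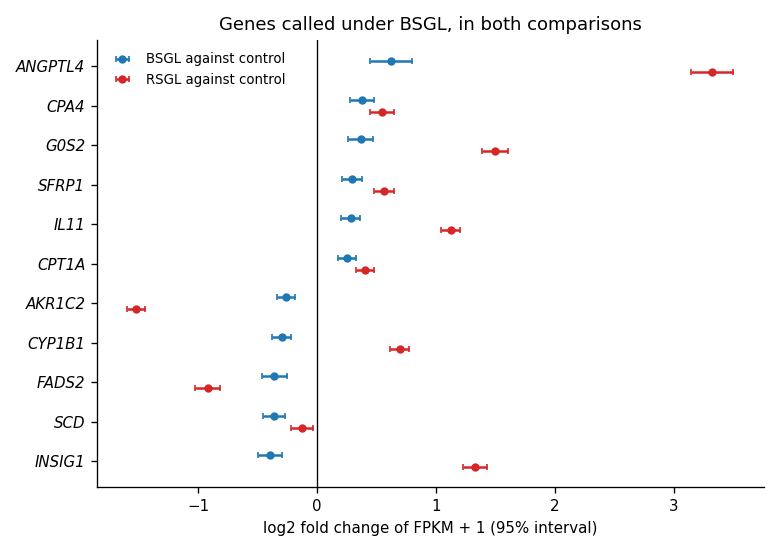
Log2 change with its 95% interval against control (points and bars, n = 3 per group, limma) for the 11 genes called under BSGL, in the BSGL and the RSGL comparison. INSIG1 (-0.40 and 1.32) and CYP1B1 (-0.30 and 0.69) lie on opposite sides of 0.

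Several of the gene lists moved together under BSGL by small amounts. Of the 14 genes of fatty acid synthesis, SCD and FADS2 fell and 0 rose, with 0 higher and 4 lower when adjusted over the list alone. The list's camera test gave an adjusted p of 1.54e-05, with adjusted p = 0.11 with an estimated correlation. Their regulator SREBF1 stood at 32.7 FPKM in control and 25.9 under BSGL, which did not pass (adjusted p = 0.113), though voom called it (adjusted p = 0.000644). Of the 24 genes of cholesterol synthesis and uptake 1, INSIG1, fell and 0 rose, with 0 higher and 4 lower when adjusted over the list alone. The list had a median log2 change of -0.07 and an adjusted p of 1.54e-05. Of the 14 genes of fatty acid oxidation and PPAR targets, ANGPTL4 and CPT1A rose and 0 fell, with 4 higher when adjusted over the list alone, and the list passed with a median of 0.07 (adjusted p = 1.54e-05). PDK4, which restrains glucose oxidation, was at 32.3 and 37.9 FPKM and did not pass (adjusted p = 0.168), though voom called it too (adjusted p = 0.0153).

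Of the 25 measured NRF2 targets, genes of the antioxidant response, 22 had lower means under BSGL, with a median of -0.08 (adjusted p = 1.19e-11). Of this list AKR1C2 fell by the test over all genes, and 7 fell when adjusted over the list alone; voom also called GCLC (adjusted p = 0.00166). This list had an adjusted p = 0.0693 with an estimated correlation. Of 7 targets of the aryl hydrocarbon receptor, CYP1B1 fell, with 3 lower when adjusted over the list alone (list adjusted p = 5.13e-05). Matrix proteases and migration genes had 10 of 11 higher means (adjusted p = 7.89e-05), with 0 called over all genes and 1 higher when adjusted over the list alone. The number of lists that passed was 14 of 46, 5 upward and 9 downward. With an estimated correlation 4 passed, those of cholesterol, fatty acid oxidation, aryl hydrocarbon receptor and matrix protease genes. The medians of these lists kept their sign under each of 3 other scalings of the libraries, whereas rescaling to a common sum ended the calls of all their single genes and quantile scaling that of CYP1B1. The common sum also raised the values against the filter and pseudocount, so its losses need not come from scaling alone.

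The remaining passing lists under BSGL held 0 genes that passed over all genes, and their camera adjusted p-values ran from 0.006 to 0.0313. When adjusted over the list alone, 2 YAP/TAZ targets were higher, and 2 ferroptosis and glutathione genes, 3 of xenobiotic metabolism and 1 LXR target were lower. Each of these lists was lost with an estimated correlation. Upward were cytosolic ribosomal proteins (median 0.05, adjusted p = 0.65 with an estimated correlation), YAP/TAZ targets (0.05, adjusted p = 0.248 with an estimated correlation) and checkpoint ligands (0.08, adjusted p = 0.168 with an estimated correlation). Downward were ferroptosis and glutathione genes (-0.04, adjusted p = 0.119 with an estimated correlation), glycolysis (-0.02, adjusted p = 0.564 with an estimated correlation) and secretory airway genes (-0.17, adjusted p = 0.16 with an estimated correlation). Xenobiotic metabolism (-0.02, adjusted p = 0.234 with an estimated correlation) and LXR targets (-0.11, adjusted p = 0.171 with an estimated correlation) also pointed downward. The mitosis list had 0 of 25 genes changed (median 0.01, adjusted p = 0.576), with 0 when adjusted over the list alone, and its median went below 0 under a common sum and quantile scaling. The ATF4 list had 0 of 25 changed, with 1 higher when adjusted over the list alone (adjusted p = 0.885). Its median was 0.03, below 0 under a common sum, while the mean, -0.02, and the test pointed down. In the hypoxia, p53, mesenchymal, epithelial identity, surfactant and FOXO lists, which did not pass either, median and test also differed in sign.

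The 11 calls lie near the limit of the test. Each gene kept its sign in 19 of 19 alternatives. That was largely fixed in advance, since the libraries of both groups did not overlap, and leaving 1 out cannot then reverse a sign. Several other alternatives keep the same group means. Without BSGL replicate 1 there were 0 calls, and without control replicate 1 there were 2. Without control replicate 2 or 3, or BSGL replicate 2 or 3, there was 1. Of these calls, 1 each without control replicate 1, control replicate 3 and BSGL replicate 2 was among the 11, and 0 without control replicate 2 or BSGL replicate 3. There were 0 calls with no filter, a common sum, a replicate block, only the compared groups, or no trend and robust options, where limma found 813 to 1601 genes at an unadjusted p under 0.05. The 1601 came from 30093 genes, with no filter. Chance gives 639 among the 12775 genes of the main test, and more where more genes are tested. The spread is that between these samples, which the labels do not describe as separate cultures.

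The comparison of RSGL with control asks the same question of the other compound. RSGL changed 54.8% of the genes tested. GDF15, a cytokine released under cell stress, rose from 32.5 ± 1 to 269.1 ± 2.8 FPKM (SD, n = 3), and PLIN2, the coat protein of lipid droplets, from 15.8 ± 0.733 to 121.8 ± 4.99 FPKM. CYP24A1, which degrades vitamin D, fell from 56.3 ± 2.93 to 3.82 ± 0.32 FPKM, and IGFBP3, which binds insulin-like growth factors, from 138.9 ± 6.26 to 28.7 ± 1.47 FPKM. Genes of DNA replication, mitosis and repair fell in nearly all cases, while targets of the amino acid stress factor ATF4 and of the ERK pathway rose. As lists, repair genes had adjusted p = 0.0994 with an estimated correlation and ERK genes adjusted p = 0.0716 with an estimated correlation, so neither kept its call there. In all, limma with Benjamini-Hochberg adjustment called 7005 of 12775 genes, 3478 higher and 3527 lower, of which 229 rose and 181 fell by at least 2-fold. The 3 RSGL libraries lay apart from the 3 control libraries in 6854 of the called genes and in 61.2% of all genes, where chance gives 10%.

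The largest rises were those of the cytokine IL24, from 0.129 to 11.8 FPKM (log2 interval 3.29 to 3.71, adjusted p = 3.02e-09), ANGPTL4 (3.32, SE 0.0798), GDF15 (3.01, SE 0.0405), PLIN2 (2.87, SE 0.0464), DUSP5, a nuclear phosphatase of ERK (2.86, SE 0.0545), and SLC16A6, of the monocarboxylate transporter family (2.63, SE 0.0371). The largest falls were those of CPLX2, a complexin of vesicle release, from 19.6 to 0.547 FPKM (-3.74, SE 0.0869, adjusted p = 1.58e-09), CYP24A1 (-3.57, SE 0.0552), DIRAS3, a Ras-family GTPase (-2.65, SE 0.0785), CPS1, an enzyme of the urea cycle (-2.65, SE 0.0664), IGFBP3 (-2.24, SE 0.0445) and SAMD11 (-2.19, SE 0.0886). HMOX1, heme oxygenase, rose from 62.4 to 377.3 FPKM (2.58, SE 0.0338).

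IL24 (gene ID 11009) lies on chromosome 1 at 206897404 to 206904139, GDF15 (9518) on chromosome 19 at 18386158 to 18389176 and PLIN2 (123) on chromosome 9 at 19108391 to 19127606. DUSP5 (1847) lies on chromosome 10 at 110497867 to 110511544, SLC16A6 (9120) on chromosome 17 at 68267026 to 68291264 and CPLX2 (10814) on chromosome 5 at 175796539 to 175884021. CYP24A1 (1591) lies on chromosome 20 at 54145731 to 54173985, DIRAS3 (9077) on chromosome 1 at 68045962 to 68051762 and CPS1 (1373) on chromosome 2 at 210477682 to 210679107. IGFBP3 (3486) lies on chromosome 7 at 45912245 to 45921272, SAMD11 (148398) on chromosome 1 at 925741 to 944581 and HMOX1 (3162) on chromosome 22 at 35381067 to 35394214.

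**Figure D3:**
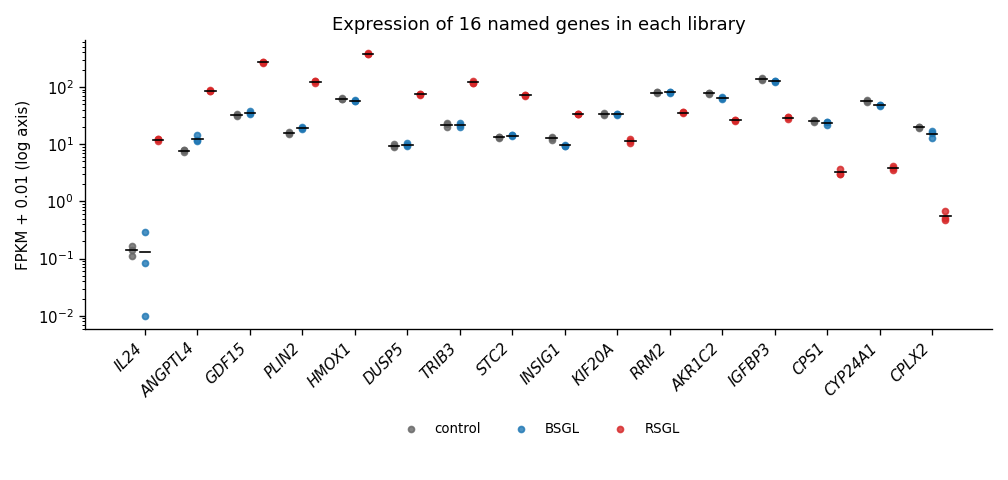
Expression of named genes in the control, BSGL and RSGL libraries, as FPKM + 0.01 on a log axis; each point is 1 library and each line a group mean (n = 3). GDF15 and PLIN2 stand apart upward and CYP24A1 and CPLX2 downward in the RSGL libraries.

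Genes of cell division fell together under RSGL. All 25 genes of G2/M and mitosis fell, with a median of -0.84 (adjusted p = 6.91e-16). KIF20A, a mitotic kinesin, fell from 33.6 to 11.3 FPKM (log2 -1.49, SE 0.0501), MKI67, the marker of cycling cells, from 40.5 to 16.6 FPKM, and CENPF, a kinetochore protein, from 28.1 to 12.1 FPKM. Of 30 genes of S phase and DNA replication 29 fell and 0 rose (median -0.66, adjusted p = 1.84e-14). RRM2, a subunit of ribonucleotide reductase, fell from 79.4 to 35.6 FPKM, and MCM4, of the replicative helicase, from 65.7 to 29.8 FPKM. All 20 genes of homologous recombination and DNA repair fell (median -0.52, adjusted p = 3.4e-09, and adjusted p = 0.0994 with an estimated correlation). Among these were the nuclease EXO1 (-0.92, SE 0.0493), XRCC3 (-0.81) and XRCC2 (-0.77). Counts in these 3 lists were the same under each scaling. Of 9 replication-dependent histones 6 fell and 1 rose (adjusted p = 0.0317, and adjusted p = 0.135 with an estimated correlation), and the riser was lost under a common sum.

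Stress and growth factor signalling genes rose. Of 25 targets in the list of ATF4 and the amino acid stress response 22 rose and 1 fell, with a median of 0.85 (adjusted p = 7.12e-11), and 21 rose under a common sum or quantile scaling. TRIB3, a pseudokinase induced by ATF4, rose from 21.8 to 119.4 FPKM (log2 2.40, SE 0.0642), STC2, a secreted glycoprotein, from 13.3 to 71.6 FPKM, DDIT3, the factor CHOP, from 14.0 to 61.5 FPKM, and ASNS, which makes asparagine, from 44.5 to 143 FPKM. ATF4 itself rose from 110.7 to 200.4 FPKM, and SLC7A11, the cystine transporter, fell (-0.35). Of 20 genes of ERK pathway output 18 rose and 0 fell, with 19 higher when adjusted over the list alone, and 17 rose under a common sum (median 0.72, adjusted p = 1.94e-09, and adjusted p = 0.0716 with an estimated correlation). They included DUSP6, a phosphatase of ERK, from 2.88 to 10.0 FPKM, FOSL1, a partner of JUN, from 42.2 to 121.1 FPKM, and EREG, an EGF receptor ligand (log2 1.47, SE 0.0352). Of 14 immediate early genes 13 rose and 1, JUNB, fell (median 0.75, adjusted p = 6.59e-06). JUN rose from 18.4 to 72.2 FPKM, DUSP1, a phosphatase of MAP kinases, from 70.5 to 219.6 FPKM, and KLF6 from 13.2 to 27.9 FPKM. Of the 46 lists 21 passed, 10 upward and 11 downward. With an estimated correlation 4 passed, those of G2/M, S phase, ATF4 and immediate early genes.

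Several defence lists fell as lists, with exceptions among their members. Of 22 type I interferon response genes 17 fell, with 18 lower when adjusted over the list alone, and 1, OAS1, rose (adjusted p = 5.65e-05, and adjusted p = 0.122 with an estimated correlation). IFI6 fell from 23.2 to 12.6 FPKM, IFIT1 from 33.2 to 18.9 FPKM and HERC5 from 13.6 to 8.43 FPKM. Of 25 NRF2 targets 17 fell and 5 rose (median -0.36, adjusted p = 0.000345, and adjusted p = 0.199 with an estimated correlation), and 3 rose under a common sum or quantile scaling. Among those that fell were GCLC, which makes glutathione, from 74.7 to 27.4 FPKM, AKR1B10, from 373.5 to 140.3 FPKM, and the AKR1C copies AKR1C2 (-1.52) and AKR1C3 (-1.44). Those that rose were HMOX1, the ferritin chains FTH1, from 2330 to 4454 FPKM, and FTL, and with small changes AKR1C1 and TXNRD1. HMOX1 and FTH1 rose under all 4 scalings. Of 17 heat shock genes 11 fell, with 12 lower when adjusted over the list alone, and 1, HSP90AA1, rose, which was lost under a common sum and quantile scaling (adjusted p = 0.00115, and adjusted p = 0.122 with an estimated correlation). DNAJB4 (-0.59), DNAJA1 (-0.51) and HSPA8 (-0.33), all chaperones, fell.

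Other lists that passed rose in part. Matrix proteases and migration genes had 8 of 11 higher and 1 lower (adjusted p = 0.00106, and adjusted p = 0.0716 with an estimated correlation), with the lysosomal protease CTSL at 105.5 and 307.1 FPKM. Hypoxia response genes had 10 of 17 higher and 2 lower, and 9 higher under a common sum or quantile scaling (adjusted p = 0.00887, and adjusted p = 0.135 with an estimated correlation). VEGFA, the vascular growth factor, rose from 15.6 to 63.4 FPKM, while EGLN3 (-1.35) and EGLN1 (-0.78), which turn over the hypoxia factor, fell. Autophagy and lysosome genes had 13 of 23 higher and 3 lower (adjusted p = 0.0126, and adjusted p = 0.286 with an estimated correlation), with MAP1LC3B, the autophagosome marker, at 17.6 and 36.9 FPKM. Ferroptosis and glutathione genes had 11 of 17 higher and 3 lower (adjusted p = 0.0121, and adjusted p = 0.113 with an estimated correlation). Of 7 checkpoint ligands 5 rose (adjusted p = 0.0146, and adjusted p = 0.122 with an estimated correlation), among them CD274, or PD-L1, from 1.11 to 4.03 FPKM. Sphingolipid genes had 10 of 19 higher and 2 lower, and 5 higher under a common sum (adjusted p = 0.0227, and adjusted p = 0.122 with an estimated correlation), with UGCG, which makes glucosylceramide, at 7.59 and 21.9 FPKM. Of 30 cytosolic ribosomal proteins 18 rose and 0 fell, with 9 higher under quantile scaling (median 0.14, adjusted p = 0.00144, and adjusted p = 0.611 with an estimated correlation).

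The last lists to pass fell by small amounts or held few genes. Of 25 genes of MYC and ribosome biogenesis 14 fell and 2 rose (median -0.13, adjusted p = 0.0196, and adjusted p = 0.289 with an estimated correlation). Of 26 proteasome genes 13 fell and 2 rose (median -0.15, adjusted p = 0.0405, and adjusted p = 0.612 with an estimated correlation), and 1 rose under a common sum. Of 4 secretory airway genes 3 fell, with 4 lower when adjusted over the list alone (adjusted p = 0.0196, and adjusted p = 0.122 with an estimated correlation), among them AGR2 from 52.2 to 23.7 FPKM. Of 11 xenobiotic metabolism genes 5 fell and 1 rose (adjusted p = 0.0271, and adjusted p = 0.198 with an estimated correlation), with ALDH1A1 at 1961 and 762.1 FPKM.

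Lipid genes moved both ways under RSGL. Of 14 genes of fatty acid oxidation and PPAR targets 7 rose and 2 fell, and 5 rose under a common sum (median 0.11, adjusted p = 0.111). Of 14 genes of fatty acid synthesis 3 rose and 8 fell (adjusted p = 0.177), with ELOVL6, an elongase, rising by 0.68 on the log2 scale, and FADS2 at 54.2 and 28.2 FPKM. Of 24 genes of cholesterol synthesis and uptake 7 rose and 7 fell, and 6 rose under a common sum (adjusted p = 0.944). In this list INSIG1 rose from 12.8 to 33.5 FPKM and HMGCS1, an early enzyme of the pathway, fell from 16.4 to 10.5 FPKM. The median of the cholesterol list was 0.02, or -0.02 under a common sum, its mean lay just below 0, and its test pointed up. Of the other lists that did not pass, p53 targets had a median of -0.02 and a mean of 0.16, chaperones of the endoplasmic reticulum had a median just below 0 and a mean of 0.08, and LXR targets had a mean of 0.01 while the test pointed down.

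**Figure D4:**
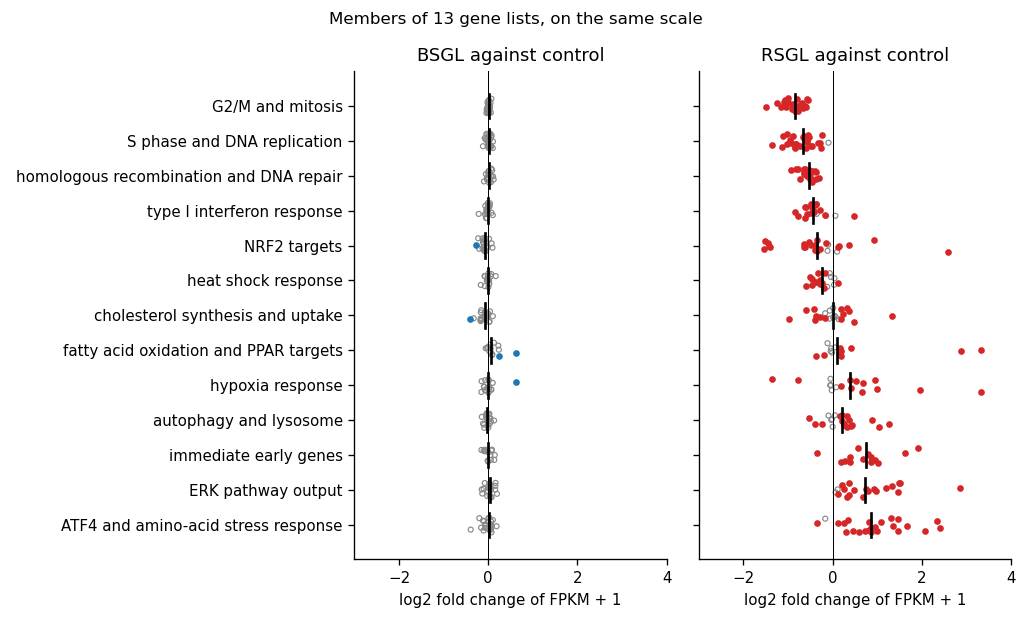
Log2 change against control of the members of 13 gene lists under RSGL and under BSGL; each point is 1 gene on a primary chromosome, filled where its adjusted p was under 0.05 and open where not, and the black line is the median of the points (n = 3 libraries per group). Under RSGL all points of G2/M lie below 0 and are filled, while under BSGL its points are open and lie around 0.

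The direct comparison of both compounds, at the same dose and time, asks where their effects differ. Cell division genes were higher under BSGL than under RSGL, with KIF20A at 33.4 and 11.3 FPKM (log2 1.49) and MKI67 at 41.4 and 16.6 FPKM (1.28). HMOX1 was lower under BSGL, at 57.0 ± 1.85 and 377.3 ± 7.37 FPKM (SD, n = 3), a log2 difference of -2.71 (SE 0.0338, adjusted p = 8.81e-11). EDN1, the precursor of the vasoconstrictor endothelin, was higher under BSGL, at 30.1 and 6.23 FPKM (2.11, SE 0.0534, adjusted p = 3.26e-09). In all, limma with Benjamini-Hochberg adjustment called 6904 of 12775 genes, 3517 higher and 3387 lower under BSGL, of which 167 were higher and 194 lower by at least 2-fold. The libraries of the compounds lay apart in 6797 of the called genes and in 61.2% of all genes, where chance gives 10%.

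The largest differences toward BSGL were those of CPLX2 (3.36, SE 0.0869), CYP24A1 (3.34, SE 0.0552), DIRAS3 (2.59), CPS1 (2.53), EDN1 and IGFBP3 (2.10). Those toward RSGL were IL24 (-3.52, SE 0.0925), GDF15 (-2.89), DUSP5 (-2.82), HMOX1, ANGPTL4 (-2.70) and SQSTM1, a carrier of autophagy cargo (-2.73, SE 0.871, adjusted p = 0.0369). The SQSTM1 value is uncertain, because the table places the gene outside the primary chromosomes and its mean of 39.8 FPKM under RSGL has an SD of 36.2. EDN1 lies on chromosome 6 at 12256464 to 12297194.

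Of the 46 lists 23 differed between the compounds, 13 higher and 10 lower under BSGL. All 25 genes of G2/M (adjusted p = 2.31e-16) and 29 of 30 of S phase (adjusted p = 4.2e-15) were higher under BSGL, and 22 of 25 of ATF4 (adjusted p = 3.6e-12) were lower, with 1 higher. Of 14 immediate early genes 12 were lower and 1 higher, with 13 lower when adjusted over the list alone (adjusted p = 3.26e-06). These are the 4 lists that passed with an estimated correlation. All 20 genes of homologous recombination and DNA repair were higher under BSGL (adjusted p = 1.22e-09) and 18 of 20 of ERK output lower, with 19 lower when adjusted over the list alone (adjusted p = 1.16e-09). Each of these had adjusted p = 0.0799 with an estimated correlation. Interferon response genes had 16 of 22 higher and 1 lower under BSGL (adjusted p = 0.00012, and adjusted p = 0.138 with an estimated correlation). NRF2 targets had 16 of 25 higher and 6 lower, with 17 higher when adjusted over the list alone (adjusted p = 0.00171, and adjusted p = 0.245 with an estimated correlation). Heat shock genes had 12 of 17 higher under BSGL (adjusted p = 0.000887, and adjusted p = 0.138 with an estimated correlation), and hypoxia genes 10 of 17 lower and 2 higher, with 12 lower when adjusted over the list alone (adjusted p = 0.00314, and adjusted p = 0.138 with an estimated correlation). In p53 targets, which did not pass, the median was 0.01 while the mean, -0.18, and the test pointed down. The test also pointed down in chaperones of the endoplasmic reticulum (median 0.07) and glucocorticoid receptor targets (median 0.09), which did not pass.

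Lipid lists held many genes that differed between the compounds, but camera did not set them apart from other genes. By fry, which makes no comparison with other genes, 42 of 46 lists passed, so that passing singles out few lists. The lists of cholesterol (fry adjusted p = 1.64e-05) and fatty acid oxidation (fry adjusted p = 3.28e-06) pointed lower under BSGL. That of fatty acid synthesis did not pass (fry adjusted p = 0.173). Cholesterol genes had 7 of 24 higher and 10 lower under BSGL (adjusted p = 0.449), fatty acid synthesis genes 6 of 14 higher and 5 lower (adjusted p = 0.673), and fatty acid oxidation genes 4 of 14 higher and 6 lower (adjusted p = 0.385). FADS1, a desaturase, did not differ detectably between the compounds, with a log2 difference of 0.05 (95% interval -0.01 to 0.12, adjusted p = 0.168), nor did HADHA, an enzyme of fatty acid oxidation (0.01, interval -0.09 to 0.10). PDK4 was higher under BSGL, at 37.9 and 32.1 FPKM (0.24, adjusted p = 0.000955).

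All 11 genes called under BSGL were also called under RSGL. In 9 of them the direction was the same, 6 higher and 3 lower, where the counts alone would give 3.01 for independent comparisons. In 100 simulations of unchanged groups with the same control libraries, 66.2% of these genes had the same sign in both comparisons. The simulated values were not selected for large BSGL changes, as the real ones were, so this share is too low a reference for the 9. In the simulations 0 genes were called in the same direction in both, as unchanged groups give few calls of any kind. The controls were too few to split, so part of the overlap may come from the shared control libraries. CYP1B1 and INSIG1 moved in opposite directions. The size differed in each of the 11 by the direct test, with a difference of -2.70 for ANGPTL4, -0.15 for CPT1A (adjusted p = 0.00381), 0.56 for FADS2 and 1.26 for AKR1C2. SCD lay lower under BSGL, at 73.8 FPKM, than under RSGL, at 87.3 FPKM (-0.24, adjusted p = 0.000795). Across all genes, which are not independent, the log2 changes of the compounds had a Pearson correlation of 0.271, against 0.497 in simulations of unchanged groups. The simulated correlation is set by the shared controls, and the wider spread of RSGL changes (SD 0.422, BSGL 0.154) can lower the real one. These correlations therefore do not measure shared effects. The covariance of the log2 changes was 0.0175, against 0.0097 simulated. The count of 9 depends on single libraries. It was 0 without control replicate 2, BSGL replicate 1 or RSGL replicate 2, 1 without control replicate 1 or 3 or BSGL replicate 2 or 3, 2 without RSGL replicate 1 and 4 without RSGL replicate 3, and 0 with a replicate block.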

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

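The direct test was planned, and of the tests counted here voom and the restriction to primary chromosomes were chosen only after the result was seen. The direct test between the compounds set apart 2 genes called in opposite directions against control. Opposite calls make this difference larger than either change, so that it passed adds no independent support. INSIG1 stood at 12.8 ± 0.825 FPKM in control, 9.46 ± 0.215 under BSGL and 33.5 under RSGL (SD, n = 3), with a BSGL minus RSGL log2 difference of -1.72 (SE 0.0453, 95% interval -1.82 to -1.62, adjusted p = 3.39e-09 by limma). CYP1B1 stood at 106.7 ± 3.92 FPKM in control, 86.4 ± 0.442 under BSGL and 173 under RSGL, with a difference of -0.99 (SE 0.0362, interval -1.07 to -0.91, adjusted p = 2.3e-08). The falls under BSGL are the weaker side of each pair, since they passed in at most 9 of 19 alternatives. No explanation was tested for either gene.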

How the results depend on the processing

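The tests added after the result was seen were voom, the restriction to primary chromosomes, the list tests without single libraries and splits of the libraries. The others were planned. The count models, planned for raw counts, were not run because the table holds FPKM, though the recovered fragments would have allowed them. The BSGL count of 11 became 0 with no filter (30093 genes tested, 1601 at an unadjusted p under 0.05), with a common sum (15396 tested, 859), with a replicate block (813), with the 2 compared groups only (871), with no trend or robust option (877) and at 2-fold, and 31 with voom, 10 higher and 21 lower, which shared 10 of the 11. Only the fold change limit has a known cause; for the others the cause was not tested. It was 15, 6 higher and 9 lower, at FPKM of 5 and again for protein-coding genes, 11 with median-of-ratios scaling, and 0 to 2 without 1 library: 0 without BSGL replicate 1, 2 without control replicate 1, 1 for the rest. The RSGL count of 7005 was 410 and the BSGL against RSGL count of 6904 was 361 at 2-fold; other alternatives gave 5041 to 7279 and 5020 to 7164, and leaving out 1 library 6294 to 6545 and 6166 to 6445. With the replicate block these were 6792 and 6696. No pairing by replicate number was seen: 6 of 18 best matches had their own number, the share that chance gives. This does not exclude a pairing. The overlap of 9 became 0 at 2-fold and 0 with the block, stayed 9 with median-of-ratios scaling and a pseudocount of 0.1, and was 0 to 4 without 1 library: 0 without control replicate 2, BSGL replicate 1 or RSGL replicate 2, 1 without control replicate 1 or 3 or BSGL replicate 2 or 3, 2 without RSGL replicate 1 and 4 without RSGL replicate 3. Lists passing under BSGL (14), RSGL (21) and between compounds (23) became 4, 4 and 4 with an estimated correlation, and 9, 45 and 42 with fry, which does not compare a list with other genes; without 1 library they were 10 to 13, 19 to 21 and 19 to 22. Of the named genes' values under alternatives, 75 lost the call under BSGL and 35 kept it, 320 kept it under RSGL, and between compounds 313 kept it and 7, all SQSTM1, lost it. No sign was reversed, which leaving out 1 library could not do, since genes were named only where the libraries did not overlap. Other splits of 6 libraries, 10 per comparison, are too few for a share under 0.05; the real split alone (1) gave 11, 7005 and 6904 genes, against at most 3, 1 and 1. Depth limits genes near 1 FPKM. In simulation 44% of BSGL changes of log2 0.25 were found, beside larger changes that ease the adjusted threshold and with 1 dispersion for all genes. The share found among real BSGL changes may be lower.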

Other observations

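The tests of the 3 patterns weighed here were chosen only after the results were seen, while the gene lists were planned. Several lists that did not pass as a whole under RSGL held members with large opposite changes (limma, n = 3 per group). Of 22 genes of extracellular matrix and integrins 10 rose and 6 fell. ITGA3, an integrin chain that binds laminin, rose from 116.5 to 456.9 FPKM and ITGA2 from 6.30 to 24.1 FPKM, while the collagen COL5A1 fell (log2 -0.89). Of 22 mesenchymal and TGF-beta response genes 7 rose and 11 fell. TGFBI fell from 278 to 86.9 FPKM and the feedback inhibitor SMAD7 by 0.72 on the log2 scale, while the integrin chain ITGA5 rose (0.89). Of 13 receptor tyrosine kinases and ligands 7 rose and 4 fell, with EGFR at 17.1 and 33.1 FPKM and FGFR3 falling (-1.08).

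Of 20 glycolysis genes 6 rose and 13 fell under RSGL, with the lactate dehydrogenase LDHA falling from 720 to 440.6 FPKM and the glucose transporter SLC2A1 rising from 34.2 to 55.0 FPKM. Of 13 mitochondrially encoded transcripts 2 rose and 7 fell, and 1 rose under quantile scaling, with COX3 falling from 5554 to 3266 FPKM and ND4 rising (0.27). Ribosomal RNA of mitochondria made up 0.847 to 0.956% of fragments in the control and BSGL libraries and 1.34 to 1.38% in the RSGL libraries. Of 21 NF-kB and inflammatory cytokine genes 11 rose and 7 fell, with 8 lower when adjusted over the list alone. The chemokine CXCL1 fell from 85.1 to 25.2 FPKM and CSF2 rose from 0.749 to 4.97 FPKM. Of 23 p53 targets 6 rose and 7 fell, with the cell cycle inhibitor CDKN1A at 87.0 and 123.8 FPKM and MDM2, which degrades p53, falling by 0.11. Of 20 chaperones and genes of the unfolded protein response 7 rose and 7 fell, with 8 lower when adjusted over the list alone or under a common sum, and DNAJB9 rose by 0.93 and CALR fell by 0.43.

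The first pattern was the absence of lung lineage genes beside abundant genes of lines with mutant KEAP1, in every library. The tables argue against filtering by the authors, since 9 of 9 lineage genes are listed. They argue against reads lost to near-identical copies, since 0 of the 7 that have no such copy passed the filter. Against RSGL libraries from another line than the control libraries speaks that 1 gene, IL24, was on in 1 group and off in the other. On means at least 5 FPKM in every library and off under 0.5 FPKM in every library. CPLX2, at 19.65 FPKM in control and 0.547 under RSGL, and DIRAS3, at 9.29 and 0.642, lay just outside these limits. A mislabelled cell line stays open, and cannot be told apart from a changed H441 stock, because the 0 of 9 lineage genes past the filter are the pattern itself. CDKN2A and CDKN2B, deleted in A549 and H460, had 0 fragments in all 9 libraries, which allows up to 3 fragments per library for counting error only, while their neighbour MTAP had 1.85 to 2.59 FPKM. No test told A549 from H460.

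The second pattern was a wide spread between replicates of the 262 tested genes that the table places outside the primary chromosomes, where 59.9% had a within-group SD over 0.2 and the median SD was 0.279, against 0.0716 for primary genes. The tables argue against low depth, since primary genes matched on expression had a median SD of 0.0911, and against a single aberrant library, since at most 15.3% of these genes had their farthest value in the same library. Reads shared between near-identical copies stay open and may be the cause, since 5 of 6 pseudoautosomal genes, which have a second copy by nature, had an SD over 0.2. SQSTM1 had 4039, 4139 and 681 fragments in the control libraries. Under RSGL 22.9% of these genes were called, against 55.5% of primary genes, and no biological explanation was tested.

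The third pattern was that NRF2 targets moved both ways under RSGL. At least 3 members rose and 17 fell under each of 3 rescalings, with HMOX1 and FTH1 rising under all. A first bound of 4 risers was not met and was then lowered to 1, so this test does not decide whether the normalization was a cause. The median-of-ratios factors, 0.9936 to 1.01, were also too close to 1 to undo such changes. Without the AKR1 family and the ferritin chains 14 of 19 members fell under each scaling, which argues against shared reads for those that fell. Shared reads stay open for those that rose, since only 2 of these 19 rose. TXNRD1 was lost under a common sum (adjusted p = 0.124) and quantile scaling (adjusted p = 0.0624), which left 1, HMOX1. KEAP1, which marks NRF2 for degradation, fell from 34.1 to 18.8 FPKM, NFE2L2, which encodes NRF2, from 19.6 to 17.2 FPKM, and BACH1, a repressor of HMOX1, rose from 3.08 to 4.06 FPKM. Lower activity of all targets stays open as a part of the cause, because the 5 of 25 members that rose are the pattern itself and test nothing, and no other biological explanation was tested.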
